A study of Mus musculus with 9 samples.

How the data were processed

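Chromatin immunoprecipitation and sequencing (ChIP-seq) had been carried out on mouse C57BL/6 acute myeloid leukaemia cells carrying the MLL-AF9 fusion, sorted for GFP after lentiviral infection with a control or a Kdm1a knockdown virus. The 9 libraries cover 4 histone marks, H3K4me2, H3K4me3, H3K9me2 and H3K9me3, each in control and in knockdown cells, and an input of sheared genomic DNA from knockdown cells. Groups were taken from the sample titles, and each group holds 1 library. The reads were sequenced on a SOLiD instrument per the labels' protocols, and they were aligned with Bowtie to build NCBIM37 per the submitters' processing notes, which give no version. Mapping filters and the treatment of repeat reads are not given in the sources used here.

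Each library came with a file of aligned reads and a table of genes. The read files list 1 read per line at a length of 48 bp, and reads that repeat a start position are kept in them. The deposited tables give 15920 Ensembl genes with 14 windows per gene, namely 2.5 to 10 kb upstream, the nearest 2.5 kb upstream, 10 equal parts of the gene, and the corresponding pair of downstream windows. Every table also assigns each gene to one of 4 classes. The class named MLL holds 114 genes and was taken as the genes bound by MLL-AF9 that the design text describes. TOP (4741 genes), MIDDLE (6323) and BOTTOM (4742) were taken as the unbound genes of high, middle and low expression. The expression values behind these classes were not used here.

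The deposited values behave as RPKM, reads per kb of window divided by a constant for each library, as read from the values themselves since no source names the unit. In the 2.5 kb windows 100% of the values were whole multiples of the value of 1 read within 0.1 read. The width of the gene parts was found per gene from the steps between values over all libraries, which failed for 44 genes, 24 of MIDDLE and 20 of BOTTOM. With these widths at least 99.995% of all window values of a library came out as whole reads within 0.1 read. The constants, as reads, were 5100000 and 2800000 for H3K4me2 control and knockdown, 6000000 and 2600000 for H3K4me3, 6600000 and 4150000 for H3K9me2, 3700000 and 4300000 for H3K9me3, and 6100000 for the input. They are not the read totals of the read files, which are 0.789 to 3.005 times as large, and how they were set is not stated. The recovered reads were therefore scaled to the reads of each library's own read file. No counts model was fitted, as no group has a second library.

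For the H3K4 marks the main window was the nearest 2.5 kb upstream together with the part of the gene next to the start. For the H3K9 marks it was the gene with 2.5 kb on both sides. The log2 ratio of knockdown over control was computed on reads scaled to the total of the read file, given as RPM where a level is printed, with a prior of 2 reads shared out by library size, for genes with at least 20 reads over the pair. The bound genes were compared with all other genes by the difference of the class medians, with a 95% bootstrap interval over genes from 2000 resamples, and 500 resamples were used for large classes and for means. Its percentile was taken among 10000 random lists matched on level in 20 bins. Single genes were counted as higher or lower where they differed by more than 2-fold from the median of all genes and the exact (Clopper-Pearson) conditional binomial 95% interval excluded that median. These intervals cover counting error only, and the bootstrap intervals cover the spread over genes only; neither measures how far a second culture would differ. Reads without molecular identifiers are not independent molecules. In the log2 ratios a count of 0 entered with the prior. Only for the printed fold of a named gene was a count of 0 set to a floor of 3 reads in the library.

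The variance of reads between the adjacent parts on either side of a gene's middle, relative to counting error, was expressed as a spread factor. It is the mean of the squared difference divided by the sum, where the sum is at least 4 reads. Real changes of signal along the gene enter it. The factor was applied to the main window of each mark and, in simulations, drawn separately for each library. It ran from 1.83 in H3K9me2 control to 7.27 in H3K4me2 control. On simulated data drawn for the real genes with the real depths, 100% of 2000 window widths were recovered within 1%. With counting error alone, a 6-fold change was recovered in 100% of 98 changed genes for H3K4me2, and a 3-fold change in 86.6% of 97, while 1.09% of 13648 unchanged genes were called. With the spread factor, the recovered shares for H3K4me2 were 98.0% and 77.3%, and 16.4% of 13241 unchanged genes were called. A class shift of 0.50 put into 113 bound genes came back as 0.54 with counting error, and as 0.48 over 109 genes with the spread factor. With the spread factor it came back as 0.60 for H3K4me3, 0.53 for H3K9me2 and 0.465 for H3K9me3. These errors are not small beside the shifts reported below for those 3 marks.

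The test, the ratio and interval, the prior, the read minimum, the size rule and the alternatives on windows, priors, filters, thinning, input subtraction and scale were fixed before the data were examined. So was the rule for named genes, the 10 highest and 10 lowest per mark with at least 50 reads, ranked by the interval bound nearer to the median of all genes, with the outermost bound genes and a few genes by symbol. The planned gene lists and the always-named genes, Kdm1a among them, were given by symbol. The reference table used here, of assembly GRCm38.p6, lists no Ensembl IDs in its column for them, so 0 of the 15920 IDs matched, and the files do not pair the IDs with symbols. Those lists were therefore not used, only 4 changed genes are named by ID, and the authors' MLL class stands in for the planned list of fusion targets, as the authors' expression classes do for the planned classes by another mark. These substitutions, the scales by deposited constants, by the median 10 kb bin and without the fullest bins, the spread factor, the match on gene length and the removal of genes with high input were chosen after the data were seen. No gene coordinates of build NCBIM37 were used here, so the windows are those of the deposited tables, a fallback fixed in advance, and the narrower and wider windows of the alternatives are the nearest ones in those tables: 2.5 kb upstream, or 10 kb upstream to the next part of the gene, for the H3K4 marks, and the gene alone, or the window near the start, for the H3K9 marks.

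Read files were binned in 10 kb bins, and a bin was left out of the total in one alternative where it held over 50 times the library's median bin. The work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.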

Results

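Histone methylation was profiled in mouse acute myeloid leukaemia cells driven by MLL-AF9, an oncogenic fusion of the histone methyltransferase MLL with AF9. The cells carried either a control virus or a knockdown of Kdm1a, whose product removes methyl groups from H3K4me2 and H3K9me2 according to the design text. H3K4me2 and H3K4me3 mark active regulatory regions and promoters, and H3K9me2 and H3K9me3 mark silent chromatin. Each mark was measured once per condition, so there are no replicates and no difference could be tested against a spread between cultures. The control libraries held 9779717 reads for H3K4me2, 12396600 for H3K4me3, 11575398 for H3K9me2 and 3106242 for H3K9me3. The knockdown libraries held 3047635, 2902769, 12469300 and 3391445 reads for the same marks in that order, and the input from knockdown cells held 11641940. The design asks how each mark behaves at genes bound by MLL-AF9 compared with unbound genes of high (TOP), middle (MIDDLE) and low (BOTTOM) expression. The bound genes were longer than the rest, with a median of 66.0 kb against 24.7 kb in TOP, 19.5 kb in MIDDLE and 25.2 kb in BOTTOM.

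H3K4me2 at the MLL-AF9-bound genes was higher, relative to other genes, in the knockdown library than in the control library. Over the nearest 2.5 kb upstream and the adjoining part of the gene, the median log2 ratio of 113 bound genes lay 0.86 above that of 14091 other genes (95% interval over genes 0.71 to 1.13), or 1.82-fold. Of the 113 bound genes, 98 lay above the median of the other genes. Against the unbound classes taken singly, the bound genes stood 0.58 above TOP (0.42 to 0.86), 1.11 above MIDDLE (0.94 to 1.38) and 0.78 above BOTTOM (0.61 to 1.05) on the log2 scale. Among 10000 random lists of genes with the same H3K4me2 level, 0 reached the value of the bound genes, and the central 95% of the lists ran from -0.24 to 0.16. The lists depended on what was matched, with a median of 0.18 when matched on gene length and 0.39 (0.19 to 0.61) when matched on H3K4me3.

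On read totals, bound genes averaged 1.51 RPM per kb (reads scaled to the total of the read file) in control (1.28 to 1.77) and 1.73 in knockdown (1.54 to 1.94). TOP genes averaged 1.74 in control and 1.30 in knockdown, MIDDLE genes 1.74 and 0.956, and BOTTOM genes 0.896 and 0.561. Within a library, the mean at bound genes was 0.874 times that at TOP genes in control (0.744 to 1.01) and 1.34 times in knockdown (1.20 to 1.53). Along the gene, the ratio of knockdown to control at bound genes was highest inside the gene, at 1.27 (1.04 to 1.58) from 0.2 to 0.3 of its length. It was 1.17 in the 2.5 kb upstream (1.05 to 1.33), 1.00 in the adjoining part of the gene (0.853 to 1.18) and 0.849 in the window 2.5 to 10 kb downstream (0.741 to 0.985). In the same upstream window it was 0.740 for TOP, 0.583 for MIDDLE and 0.675 for BOTTOM. Whether bound genes gained or lost H3K4me2 in absolute terms depended on the scale. Their median log2 ratio was 0.30 on read totals, -0.47 with the constants of the deposited tables and -0.35 with the median 10 kb bin as the scale, while the median of all genes was -0.55, -1.31 and -1.19.

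**Figure D1:**
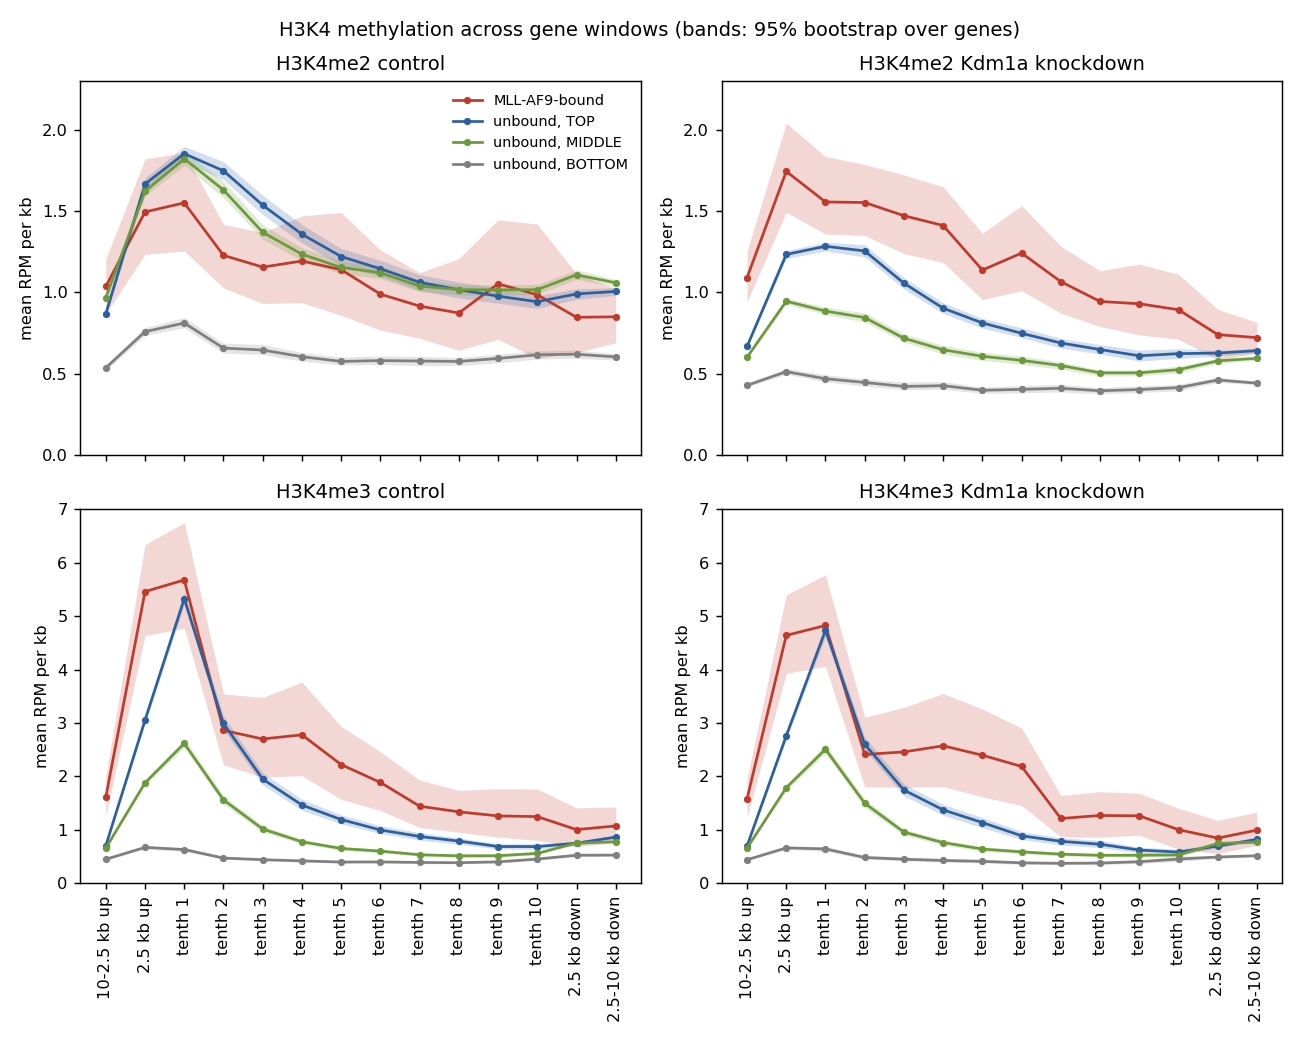
Mean H3K4me2 (upper panels) and H3K4me3 (lower panels) in RPM per kb (vertical axes) over the 14 windows of each gene (horizontal axes), in control (left) and Kdm1a knockdown (right); lines are the 4 gene classes and bands are 95% bootstrap intervals over genes. In the 2.5 kb upstream, H3K4me2 of bound genes lay below that of TOP genes in control (1.49 against 1.67) and above it in knockdown (1.74 against 1.23).

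Counted gene by gene, 48 of 113 bound genes (42.5%, exact 95% interval 33.2 to 52.1) were more than 2-fold above the median change of all genes in H3K4me2, and 2 were more than 2-fold below it. TOP genes were also more often higher than lower, 977 against 393 of 4669. MIDDLE genes went the other way, with 532 higher and 988 lower of 5915, and BOTTOM had 616 higher and 397 lower of 3507. Over all classes, 2173 genes were higher and 1780 lower of 14204. The balance depended on the processing, with 2505 higher and 3336 lower when the input was subtracted, and 882 higher and 228 lower when reads were divided by the spread factor, the measure of uneven reads inside genes. When unchanged genes were simulated with the unevenness of reads seen inside genes, 1031 of 13241 were counted higher and 1138 lower. Part of the counts in the data may thus arise with no change. The simulation drew the unevenness separately for each library, so it may overstate such counts. ENSMUSG00000028284, of the TOP class, had 54 reads in knockdown and 22 in the deeper control library, 3.37 above the median log2 ratio (counting interval 2.79 to 4.32). ENSMUSG00000059742, of BOTTOM, had 59 and 28 reads and stood 3.19 above it (2.64 to 4.02). The control level of that gene, 2.86 RPM, lay below the input at 8.50 RPM. ENSMUSG00000001027, of BOTTOM, had 0 reads in knockdown and 109 in control, at least 7.71-fold lower than the median gene when the 0 is set to 3 reads and the control count is taken without error; its counting interval, which covers both counts, ended at a log2 difference of -2.62. ENSMUSG00000043831, of MIDDLE, had 0 and 87 reads and was at least 6.15-fold lower on the same floor, with a counting interval that ended at -2.29. The input held 5.33 RPM at ENSMUSG00000001027 and 2.23 RPM at ENSMUSG00000043831, so their knockdown counts of 0 lay below the input. Whether these differences of single genes reflect the mark was not tested.

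The H3K4me2 shift of bound genes became smaller when they were set beside similar unbound genes. Against the 20 unbound genes nearest in H3K4me3, in gene length and in the ratio of input to control H3K9me2, the median difference was 0.21 (0.03 to 0.37), and it was positive for 71 of 113 genes. Once the trend on the ratio of input to control H3K9me2 was removed, bound genes stood 0.24 above TOP (0.09 to 0.37), and TOP genes likewise stood 0.24 above MIDDLE (0.21 to 0.28). The libraries themselves also differed, with 4.58% of the reads of the H3K4me2 knockdown library in 1 bin of 10 kb on chromosome 2 against 0.22% in control. For H3K4me2, H3K4me3 and H3K9me2 this split between libraries ran exactly along the conditions, so that the split and the knockdown cannot be told apart.

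Over the window near the start, mean H3K4me3 was highest at the MLL-AF9-bound genes in both conditions. In control, the mean over the same window was 5.37 RPM per kb at bound genes (4.74 to 5.99), 3.77 at TOP, 2.25 at MIDDLE and 0.739 at BOTTOM genes. In knockdown it was 4.57 (4.04 to 5.08), 3.39, 2.15 and 0.747. The excess over TOP lay mainly in the 2.5 kb upstream, at 5.46 against 3.05 in control and 4.64 against 2.76 in knockdown. The adjoining part of the gene is wider in longer genes, as the bound genes are. There the means were 5.68 (4.78 to 6.75) against 5.33 in control and 4.83 (4.06 to 5.77) against 4.73 in knockdown. By class means, the bound genes stood 8.82-fold over the input in control (5.83 to 12.8) and 7.51-fold in knockdown (5.01 to 10.9). TOP genes stood 7.17-fold and 6.44-fold over it. The mean input of bound genes, 0.608 RPM per kb, lay above their median of 0.391. By class medians, bound genes stood 11.9-fold and 10.3-fold over the input, and TOP genes 6.82-fold and 6.07-fold. How far the conditions differed in absolute terms depended on the scale, as the median ratio of knockdown to control at bound genes was 0.854 on read totals and 0.466 with the deposited constants, and that of all genes 0.927 and 0.512.

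Relative to other genes, bound genes were slightly lower in H3K4me3 in the knockdown library. Their median log2 ratio lay -0.12 from that of 13579 other genes (-0.19 to -0.058), a ratio of 0.919, and 38 of 113 lay above the median of the others. Class by class, they lay -0.066 from TOP (-0.13 to -0.0028), -0.16 from MIDDLE (-0.22 to -0.099) and -0.17 from BOTTOM (-0.25 to -0.11). That value was at percentile 0.73 of the random lists matched on H3K4me3 level. The H3K4me2 and H3K4me3 shifts of the same class thus had opposite signs and intervals that did not overlap. Of 113 bound genes, 0 were more than 2-fold higher in H3K4me3 (exact upper limit 3.21%) and 1 was more than 2-fold lower. Over all classes 615 genes were higher and 493 lower of 13692. With at least 100 reads the balance turned, to 123 higher and 175 lower. The simulation of unchanged genes with uneven reads counted more than the data did, 738 and 960 of 12766. It therefore overstated the noise between these libraries and cannot show how many of the counts arise with no change. No H3K4me3 change of a single gene is named.

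**Figure D2:**
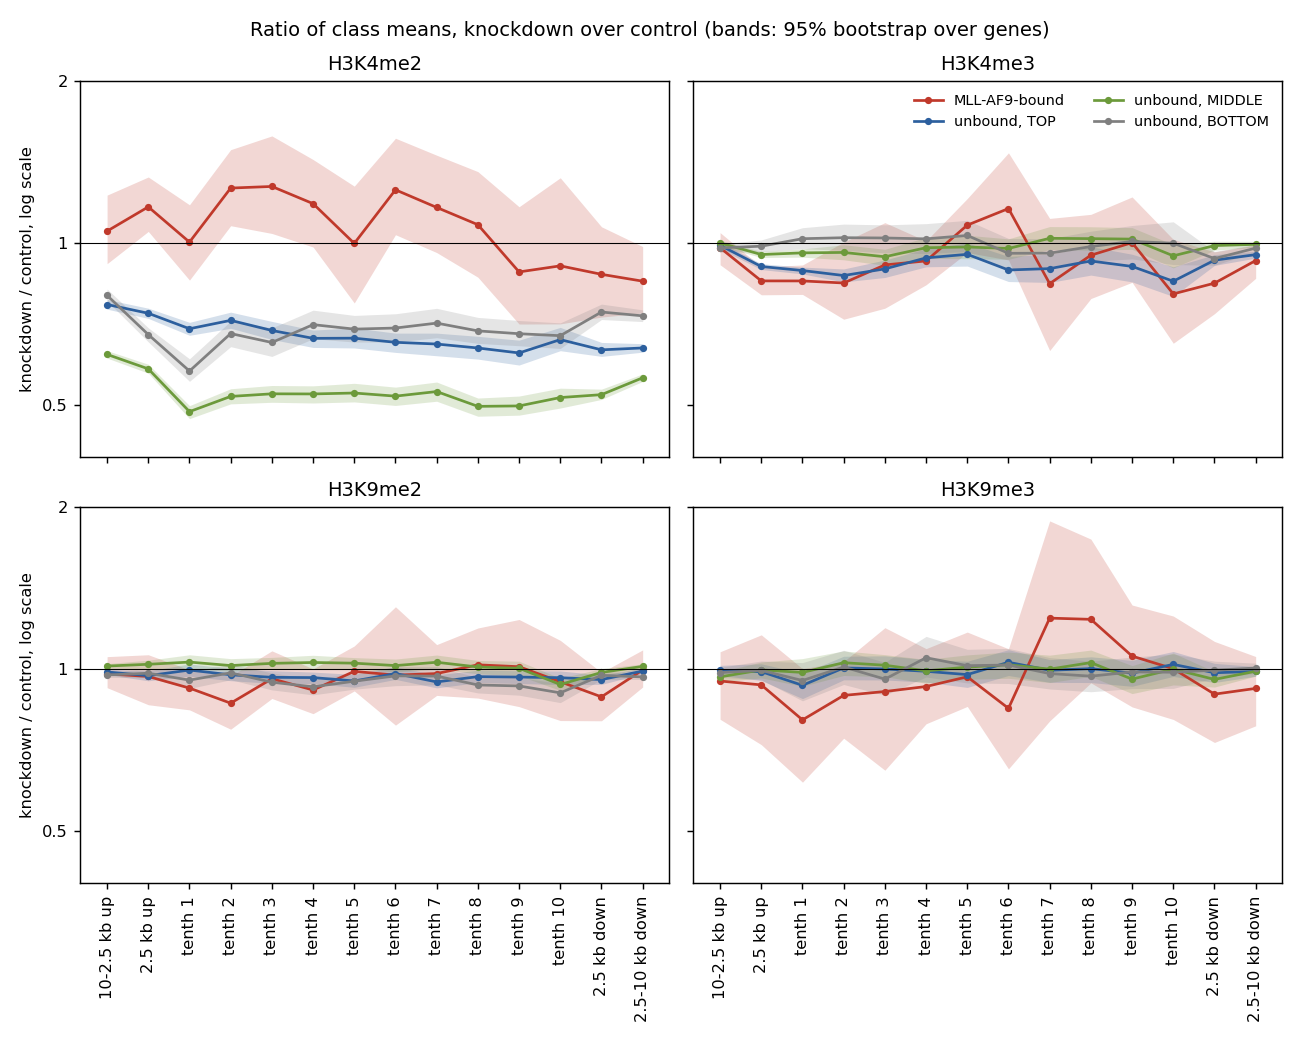
Ratio of class means, knockdown over control, on a log axis (vertical) over the 14 windows (horizontal) for each mark; lines are the gene classes and bands are 95% bootstrap intervals over genes. For H3K4me2 the bound genes lay above every unbound class in every window, while for the other marks the unbound classes lay between 0.849 and 1.05 and the bound genes between 0.804 and 1.24.

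H3K9me2, the other proposed substrate of KDM1A, was not higher at bound genes, relative to other genes, in the knockdown library. Over the gene and 2.5 kb on each side, bound genes had a median of 0.361 RPM per kb in control and 0.343 in knockdown, close to TOP genes at 0.348 and 0.331. BOTTOM genes had the highest median of the unbound classes, 0.405 in control and 0.387 in knockdown, and MIDDLE genes the lowest, 0.315 and 0.321. The median log2 ratio of 114 bound genes lay -0.066 from that of 15736 other genes (-0.11 to -0.0057), a ratio of 0.956, at percentile 1.40 of the matched random lists. Taken class by class, the interval excluded 0 against MIDDLE genes only, at -0.11 (-0.15 to -0.043), and not against TOP at -0.045 (-0.093 to 0.016) or BOTTOM at -0.043 (-0.087 to 0.018). Mean H3K9me2 was below the input in each class, at 0.803 of it in bound, 0.586 in TOP, 0.489 in MIDDLE and 0.739 in BOTTOM genes of the control.

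Of 15850 genes, 177 were more than 2-fold higher and 189 lower. The simulation of unchanged genes with uneven reads counted more than the data did, 185 and 294 of 15491. It therefore overstated the noise between these libraries too and cannot show how many of the counts arise with no change. The counts in the data depended on the processing, with 659 higher and 712 lower in the window near the start, 319 and 965 with the input subtracted, and 35 and 26 with at least 100 reads. Bound genes supplied 0 of the higher and 1 of the lower genes. With the constants of the deposited tables, the median log2 ratio of H3K9me2 over all genes was 0.71. Scaled to the reads of the read files, that median was -0.050.

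H3K9me3 at the bound genes, relative to other genes, did not differ detectably between conditions. The median log2 ratio of 103 bound genes lay 0.059 from that of 13126 other genes (-0.059 to 0.12), at percentile 84.7 of the matched lists. In the window near the start the difference was -0.13, outside that interval and opposite in sign. Median signal at bound genes was 0.333 RPM per kb in control and 0.346 in knockdown, against 0.324 and 0.322 at TOP, 0.306 and 0.305 at MIDDLE and 0.349 and 0.348 at BOTTOM genes. More than 2-fold higher were 3 bound genes and lower were 2, within totals of 511 and 467 of 13229 genes. With at least 100 reads these totals were 11 and 10. The simulation of unchanged genes with uneven reads, which may overstate such counts, gave 414 higher and 471 lower of 12285. Both libraries of this mark are shallow, with a median of 92 reads at a bound gene in control and 100 in knockdown. They were also the only pair in which both conditions had a high share of reads in the same bin of chromosome 2, 7.94% and 8.94%.

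**Figure D3:**
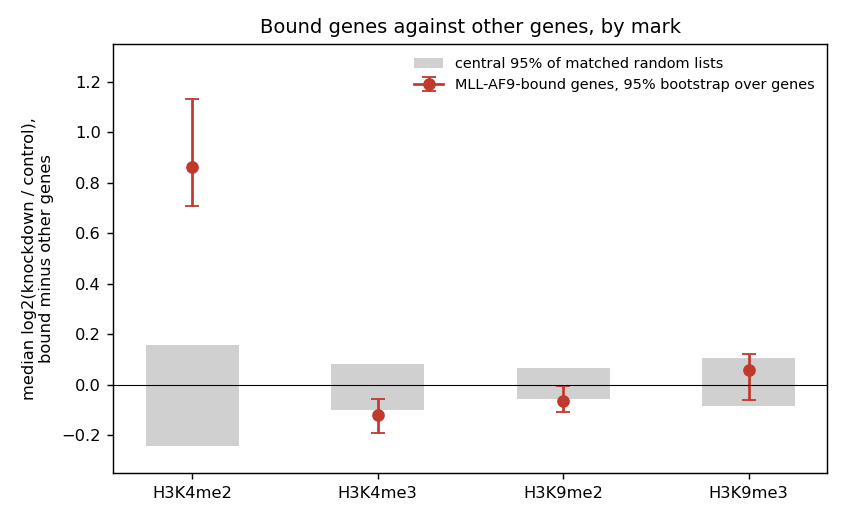
Difference between bound and other genes in the median log2 ratio of knockdown over control (vertical axis) for each mark (horizontal axis); points are the bound genes with 95% bootstrap intervals over genes, and grey bars are the central 95% of 10000 random lists matched on the level of the mark. H3K4me2 at 0.86 lay above its lists, which centre at 0.39 when matched on H3K4me3 in place of H3K4me2, H3K4me3 at -0.12 and H3K9me2 at -0.066 just below theirs, and H3K9me3 at 0.059 inside.

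**Figure D4:**
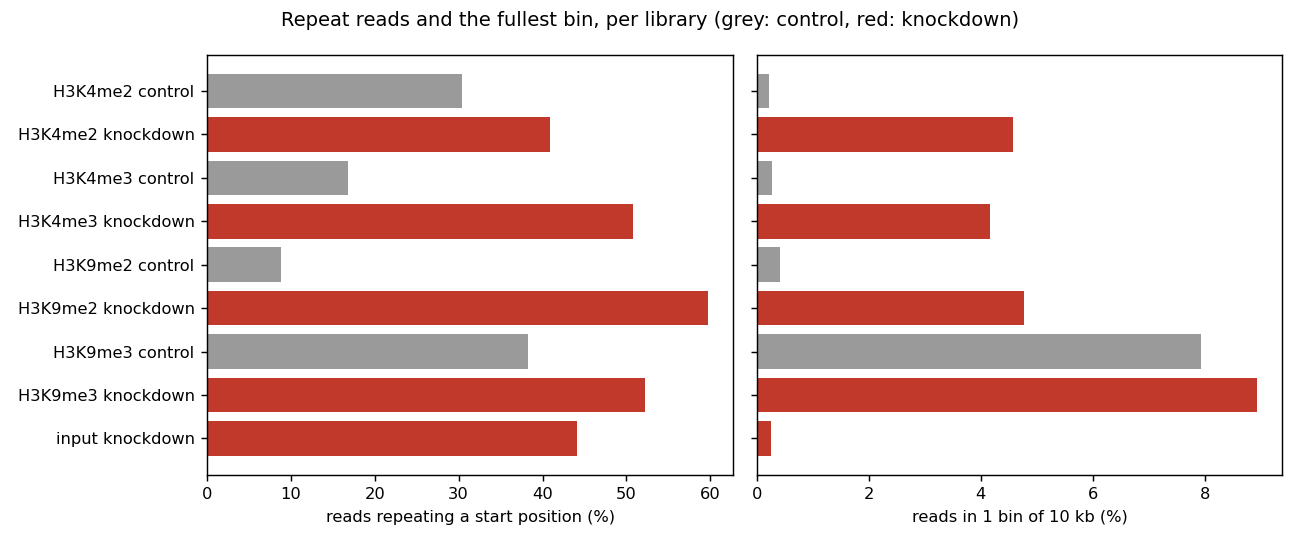
Share of reads that repeat a start position (left, percent) and share of reads in the fullest 10 kb bin (right, percent) for each library; grey bars are control and red bars knockdown libraries. Repeats ran from 8.84% in H3K9me2 control to 59.7% in H3K9me2 knockdown, and were higher in the knockdown library of each mark.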

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

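These values were looked for only after the read files had been seen, and no explanation of them was tested. A single bin of 10 kb on chromosome 2, from 98500001 to 98510000 in build NCBIM37, was the fullest bin of each of the 9 libraries. In the input it held 0.26% of the reads. It held over 2 times that share in 5 libraries. These were H3K4me2 knockdown at 4.58%, H3K4me3 knockdown at 4.16%, H3K9me2 knockdown at 4.78%, H3K9me3 knockdown at 8.94% and H3K9me3 control at 7.94%. The remaining controls stood at 0.22% for H3K4me2, 0.28% for H3K4me3 and 0.42% for H3K9me2. The bin's reads fell on few positions, for example 596614 reads on 2529 distinct starts in the H3K9me2 knockdown library. The input, although from knockdown cells, thus lay with those 3 controls, and the H3K9me3 control lay with the knockdown libraries.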

How the results depend on the processing

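The scales by deposited constants, by the median 10 kb bin and without the fullest bins, the match on gene length, the spread factor and the removal of genes with high input were chosen after the data were seen. Depth limits what single genes can show, with a median of 43 knockdown reads at a bound gene for H3K4me2. Not run were reads reduced to 1 per start position, reads outside gene windows as the scale and unmoved read ends, which need gene coordinates of the reads' build. Totals of distinct starts were tried as a scale and set aside, since the tables' reads could not be reduced in the same way.

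The difference between bound and other genes stayed within its interval over genes in 40 of 44 planned and 11 of 12 added alternatives. Those that change only the scale could hardly move it, as a scale moves every gene of a library alike. Its range was 0.68 to 1.21 for H3K4me2, -0.23 to -0.090 for H3K4me3, -0.092 to 0 for H3K9me2 and -0.13 to 0.067 for H3K9me3. For H3K4me2 this range leaves out the comparisons that lowered the difference most. It was 0.42 after removal of the trend on the ratio of input to control H3K9me2. Against the nearest unbound genes it was 0.21, and lists matched on H3K4me3 themselves had a median of 0.39. With the input subtracted it was 1.21 for H3K4me2, -0.23 for H3K4me3 and 0 for H3K9me2. Matched on gene length it was 0.68 for H3K4me2, and over the promoter window it was -0.13 for H3K9me3. The 0 for H3K9me2 follows from the method. The H3K9 marks lay below the input on average, and a gene brought to 0 reads in both libraries gets a log2 ratio of 0. The upper end of the H3K9me2 range is this 0. The cause of the other moves was not tested.

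The numbers of genes beyond 2-fold moved more, and the cause was not tested except where fewer genes or reads enter by construction. With reads divided by the spread factor, 882 higher and 228 lower for H3K4me2, 57 higher and 25 lower for H3K4me3, 84 higher and 43 lower for H3K9me2, 126 higher and 81 lower for H3K9me3 were left. With at least 100 reads they were 774 and 698 for H3K4me2, 123 and 175 for H3K4me3, 35 and 26 for H3K9me2, 11 and 10 for H3K9me3, higher and lower in that order as in what follows. Subtracting the input gave 2505 and 3336 for H3K4me2, which turned the balance of the 2 directions, 1041 and 1047 for H3K4me3 and 319 and 965 for H3K9me2. The other window gave 394 and 418 for H3K4me3, 659 and 712 for H3K9me2 and 214 and 219 for H3K9me3. For H3K4me3 the balance of 615 and 493 thus turned in the other window, as it did with at least 100 reads and with the input subtracted. Thinning the deeper library gave 376 and 281 for H3K4me3, the narrower window 289 higher for H3K9me2, and a prior of 8 reads 83 and 82 for H3K9me2 and 227 and 184 for H3K9me3.

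The median log2 ratio of all genes, which sets how a class moves in absolute terms, depended on the scale. From -0.55, -0.11, -0.050 and -0.015 in the order H3K4me2, H3K4me3, H3K9me2 and H3K9me3 it went to -1.31, -0.96, 0.71 and -0.10 with the deposited constants. It was -1.19, -0.035, 0.055 and 0.11 with the median 10 kb bin, and -0.48, -0.037, 0.032 and 0.0053 without the fullest bins. The sign thus reversed for H3K9me2 under each of these scales, and for H3K9me3 under the last 2, as the scale alone moves every gene of a library alike.

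The mean over all genes as a ratio to the input, control and knockdown in that order, was 2.68 and 1.71 for H3K4me2, 4.37 and 4.05 for H3K4me3, 0.587 and 0.575 for H3K9me2, 0.573 and 0.576 for H3K9me3. It was 2.997 and 1.88 for H3K4me2, 4.68 and 4.35 for H3K4me3, 0.594 and 0.585 for H3K9me2, 0.591 and 0.594 for H3K9me3 in the narrower window and 1.87 and 1.26 for H3K4me2, 2.08 and 1.97 for H3K4me3, 0.635 and 0.651 for H3K9me2, 0.808 and 0.845 for H3K9me3 in the other window. Without a read filter it was 2.51 and 1.62 for H3K4me2, 3.83 and 3.55 for H3K4me3, 0.587 and 0.574 for H3K9me2, 0.531 and 0.528 for H3K9me3, and with at least 100 reads 3.51 and 2.04 for H3K4me2, 6.07 and 5.54 for H3K4me3, 0.638 and 0.624 for H3K9me2, 0.688 and 0.683 for H3K9me3. Thinning gave 3.03 and 1.94 for H3K4me2, 5.25 and 4.85 for H3K4me3, 0.587 and 0.575 for H3K9me2, 0.575 and 0.577 for H3K9me3, with fewer genes kept by the filter. The median 10 kb bin as the scale gave 5.13 and 2.04 for H3K4me2, 5.30 and 5.18 for H3K4me3, 0.520 and 0.549 for H3K9me2, 0.570 and 0.625 for H3K9me3. With the input subtracted before division it was 1.73 and 0.875 for H3K4me2, 3.48 and 3.17 for H3K4me3, 0.0455 and 0.0362 for H3K9me2, 0.0363 and 0.0409 for H3K9me3, which lowers it by construction. The H3K4me2 control stayed above the H3K4me2 knockdown in each of these settings, and the H3K9 marks stayed below the input.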

Other observations

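The bound class held most of the genes with an unusually high input signal. Over the gene and 2.5 kb on each side, 5 of 15876 genes exceeded 3 times the median gene in the input, and 4 of them were among the 114 bound genes, the other being of TOP. The highest, ENSMUSG00000023764, had 11717 input reads, 24.4 times the median gene per kb. It was singled out after its value was seen. It was also high in each immunoprecipitation, at 34.5 times the median gene in H3K9me2 control, 40.4 in H3K9me3 control and 11.8 in H3K4me2 control. The mean H3K9me2 of bound genes in control, 0.497 RPM per kb with this gene included, stood above their median of 0.361.

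Unbound classes were separated less clearly by H3K4me2 than by H3K4me3, and differently in the 2 conditions. Near the start, TOP genes had 1.04 times the mean H3K4me2 of MIDDLE genes in control (1.01 to 1.06) and 1.40 times in knockdown (1.37 to 1.43). For H3K4me3 the same ratio was 1.87 in control and 1.76 in knockdown. The X chromosome took 1.90% of the reads of the H3K4me2 control library, the lowest of the 9, against 3.66% in H3K4me2 knockdown, 3.98% in H3K4me3 control and 3.26% in the input.

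The tests on the H3K4me3 pair and on the number of libraries below were chosen only after their results had been seen. The remaining tests were set before their own results but after the H3K4me2 shift of 0.86 was known, and the nearest-gene test after the results of the trend and the matched lists.

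The higher H3K4me2 at bound genes may be partly technical. The H3K4me3 pair also differed in repeats and in the fullest bin but had a shift of -0.12. This value goes against a batch shift of equal size in every mark, though the test was chosen after the value was known. It cannot decide on a batch effect that differs between marks or acts on the H3K4me2 libraries alone. The 2 pairs were also not alike, as repeats rose from 16.75% to 50.85% for H3K4me3 and from 30.38% to 40.89% for H3K4me2. Composition bias between the 2 H3K4me2 libraries was taken to be tracked across genes by the ratio of input to control H3K9me2. That assumption was not tested, and the ratio also carries H3K9me2 itself. Removing the trend on this ratio (r = -0.57 across genes, which are not independent replicates) left a shift of 0.42 (0.27 to 0.53). Against TOP genes it left 0.24 (0.09 to 0.37), down from 0.58. The shift of 0.42 lay between the limits of 0.2 and 0.43 set for this test, so the test did not decide. An imperfect tracer also leaves part of a bias in place. Random lists matched on H3K4me3 reached 0.39 (0.19 to 0.61), and with composition, H3K4me3 level and gene length matched together 0.21 (0.03 to 0.37) remained, so these properties stay open as an explanation of most of the shift. An increase of H3K4me2 at bound genes after the knockdown remains a hypothesis for all or part of the shift. Matching on these properties would also remove a knockdown effect that goes along with them. With 1 library per condition, such an increase cannot be told apart from a difference between libraries.

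H3K9me2 over all genes had a median log2 ratio of 0.71 with the deposited constants and -0.050 on the read totals. The reads of the H3K9me2 knockdown file were 3.005 times its constant, against 1.75 for the control. Which scale is the better one was not tested, as a scale moves every gene of a library alike and no library holds an outside standard.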
